A study of Fundulus heteroclitus with 20 samples.

How the data were processed

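RNA was sequenced from 20 pools of whole killifish embryos, 5 for each combination of 2 populations and 2 treatments. The series description calls the pools biological replicates. The extraction kit and an Illumina library preparation are named in the labels; the dose of PCB153 is not given in the sources used here, nor is the number of embryos in a pool.

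The deposited values were whole-number counts of fragments per gene model, 1 file per library, made by the authors with featureCounts 1.4.6 per the file headers. The headers record paired fragments, exons summed by gene, and no use of strand, on a killifish gene set of 32749 models. Options that would count multi-mapped fragments or fragments shared by overlapping genes were absent from the recorded command, so such fragments were left out by the program's defaults. Near-identical paralogs are therefore undercounted, and without strand a gene and an antisense partner cannot be told apart. FastQC, TopHat, Cufflinks, featureCounts and DESeq are listed without versions in the submitters' processing notes, whereas the alignment file named in the headers has the name and folder of another aligner, STAR, so the aligner is left open. The genome build is not given in the sources used here. Positions are those in the file headers and rows, counted from 1, on the scaffolds of that gene set; 3347 models have exons on more than 1 scaffold, and their parts are given separately.

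None of the identifiers matched the 34686 genes of the reference table used here (MU-UCD_Fhet_4.1), so no gene was named. The 33 gene lists set before the data were examined depend on names and were not applied. The rule for the genes in the text, also set before the data were examined, took the genes past the threshold with the largest fold change, an average log2 CPM of at least 1 and the same sign in both batches (for populations, in batch 2), or the smallest p where fewer than 5 qualified. Its condition on names could not be met and was dropped, and at most 2 genes per direction and comparison are printed. For the difference between responses, the gene with the smallest p in each direction is given.

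From the counts, edgeR 4.0.16 in R 4.3.3 fitted 1 quasi-likelihood model to all 20 libraries with a term for each of the 4 groups and an additive term for batch. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 22890 genes with 99.9% of all counts, and libraries were scaled by TMM. The contrasts were PCB153 minus DMSO in NBH and in SC, their difference and their mean, and NBH minus SC in DMSO and in PCB153. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. SE is the absolute log2 fold change divided by the root of the F statistic. Values per library are CPM scaled by TMM, and log2 CPM uses a prior count of 2. Responses within a batch came from a model with 8 means, 1 for each group in each batch. Calls shared by contrasts were compared with Fisher's exact test.

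Alternatives set before the data were examined were RLE and upper-quartile scaling, a weaker and a stricter count filter, DESeq2 1.42.0, limma-voom (limma 3.58.1), no batch term, no robust estimation, other thresholds, a block on population and replicate number, 1 population alone, each batch within the model of 8 means, batch 2 alone, and leaving out each library. Added after seeing the data were voom with library weights, the block without both NBH libraries numbered 4, and batch 2 without the PCB153 library of NBH replicate 4. The PCB153 library of NBH replicate 4 was kept in the reported fits because no label sets it apart.

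Pairs of libraries of the same group and batch differed by 2.65 to 77.9 times the sampling variance per gene, so none of these was a repeat of its partner. Other pairs were not compared in this way. The procedure was tested on simulated counts with 200 changed genes for each contrast named here, drawn from genes above a minimum mean count. With 20 libraries it recovered 84% of 2-fold and 49% of 1.5-fold changes for the NBH response, 76% and 49% for the SC response, and 57% and 21% for the population difference in DMSO. Without the PCB153 library of NBH replicate 4 the figures were 87% and 67%, 93% and 72%, and 86% and 48%. The simulation gave all libraries the same spread for a gene, so it held no outlying library. With 200 true changes the adjusted p is also less strict than with a few. These shares therefore do not give the power in the real data. Depth was similar across libraries (11155263 to 16438546 counts). Intervals on count ratios are exact, and a count of 0 was set to a floor of 3 counts over the group. Both cover counting error only and pool all batches of a group, so they do not separate population from batch.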

Results

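Gene expression was measured by RNA sequencing in whole embryos of the Atlantic killifish, *Fundulus heteroclitus*, from 2 populations. New Bedford Harbor (NBH) is an estuary polluted with polychlorinated biphenyls (PCBs), and Scorton Creek (SC) is a reference site. The embryos were F2 generation fish reared at 23 °C. At 10 days post-fertilization they were exposed for 6 h to the solvent DMSO or to PCB153, a polychlorinated biphenyl of the non-dioxin-like kind. Each of the 4 groups held 5 libraries, each made from a separate pool of embryos, for a total of 20 libraries. The libraries carried between 11155263 and 16438546 counts assigned to gene models, and between 25839 and 28294 of the 32749 gene models had at least 1 count. The labels place the libraries in 3 batches. Batch 1 held 3 DMSO and 3 PCB153 libraries of NBH, batch 2 held 2 libraries of each of the 4 groups, and batch 3 held 3 DMSO and 3 PCB153 libraries of SC. DMSO and PCB153 were therefore balanced in every batch, whereas the populations met in batch 2 alone. The files do not pair the gene model identifiers with names, so genes are given here by identifier and scaffold position, and their products are not stated.

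The first principal component, with 67.3% of the variance of log2 CPM, separated the NBH libraries of batch 1 from all libraries of batches 2 and 3 with 1 exception, the PCB153 library of NBH replicate 4. That library belongs to batch 2, and its deviations from the other NBH libraries of the batch had a standard deviation of 0.93 on the log2 scale, against 0.24 to 0.45 in the other 19 libraries. Within the NBH DMSO group, 13436 of 22890 tested genes differed between batch 2 and batch 1 (edgeR quasi-likelihood test, adjusted p under 0.05), of which 6492 were higher and 6944 lower in batch 2. Between batches 3 and 2 of the SC DMSO group, 264 genes differed. With that library left out, these counts were 15310 and 1553.

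**Figure D1:**
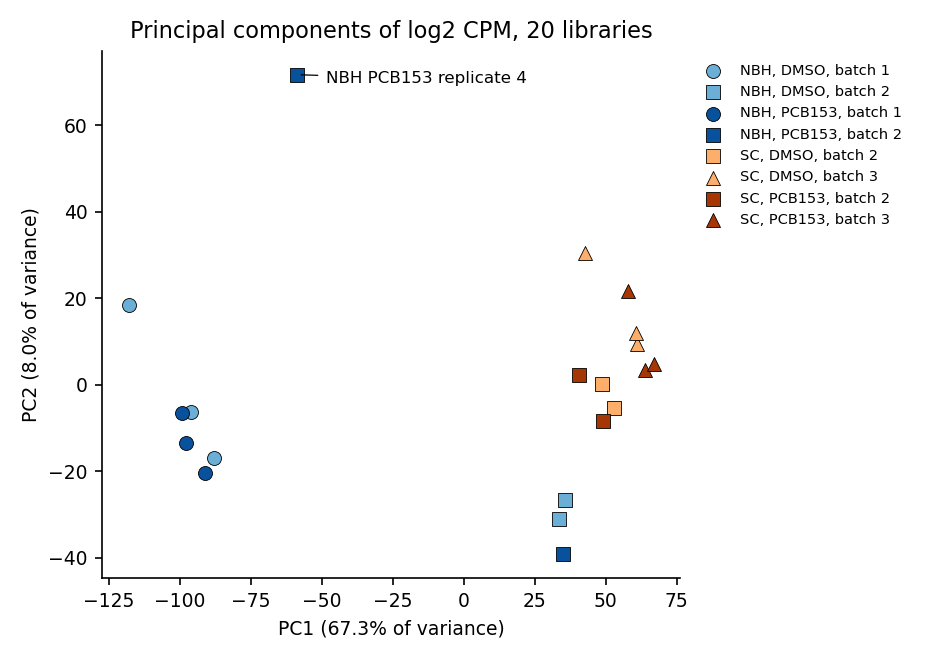
Principal components 1 and 2 of log2 CPM, in arbitrary units, for the 20 libraries; color gives the group and the symbol the batch. The NBH libraries of batch 1 lie on the left, the batch 2 and 3 libraries on the right, and the PCB153 library of NBH replicate 4 apart from both, with PC1 at 67.3% and PC2 at 8.01% of the variance.

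The first question was which genes responded to PCB153 in embryos of the polluted site. In NBH, 2 of the 22890 tested genes passed the threshold and both fell. DESeq2 called 12 genes, of the 4251 to which it gave an adjusted p, and limma-voom called 1. Funhe2EKm014979 passed in both. Funhe2EKm027226 had no adjusted p from DESeq2 and did not pass by limma-voom (adjusted p = 0.572, limma-voom). Neither of the 2 edgeR calls held in the 10 NBH libraries fitted alone, which gave 0 genes (edgeR, 598 at an unadjusted p under 0.05), with replicate number as a block or without a batch term. The log2 fold changes stayed about as large in these fits. In that order they were -0.42, -0.43 and -0.44 for Funhe2EKm014979 and -0.95, -1.01 and -1.145 for Funhe2EKm027226. Funhe2EKm014979 fell by 0.43 on the log2 scale (SE 0.06, adjusted p = 0.00776, edgeR). It fell in both batches. In batch 1 its level was 154 ± 9.05 CPM in DMSO and 112 ± 4.48 CPM in PCB153 (SD, n = 3 each), and in batch 2 it was 80.0 ± 2.75 CPM and 61.6 ± 4.93 CPM (SD, n = 2 each). The model of this gene is split over Scaffold 1047 (positions 11053 to 16603) and Scaffold 9858 (positions 599615 to 606004), with 7 exons on each. Funhe2EKm027226, on Scaffold 9909 from 2138854 to 2142736, fell by 1.02 (SE 0.15, adjusted p = 0.0183, edgeR). Its level depended on the batch more than on the exposure. It went from 1.61 ± 0.31 to 1.09 ± 0.18 CPM in batch 1 (SD, n = 3 each) and from 38.1 ± 2.04 to 16.5 ± 1.06 CPM in batch 2 (SD, n = 2 each). By edgeR, no gene passed in the upward direction. DESeq2 called 1 gene higher and 11 lower. The higher one was Funhe2EKm007817, at a log2 fold change of 0.60 (adjusted p = 0.000303, DESeq2). The smallest p among those higher in PCB153 belonged to Funhe2EKm007817 (Scaffold 305, 357828 to 382650), at a log2 fold change of 0.61 (SE 0.11, adjusted p = 0.115, edgeR), with 99.5 CPM in PCB153 and 62.7 CPM in DMSO in batch 1 and 58.4 and 40.5 CPM in batch 2. Funhe2EKm023946 (Scaffold 9870, 2152251 to 2160640) followed, at a log2 fold change of 1.05 (SE 0.21, adjusted p = 0.24, edgeR).

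**Figure D2:**
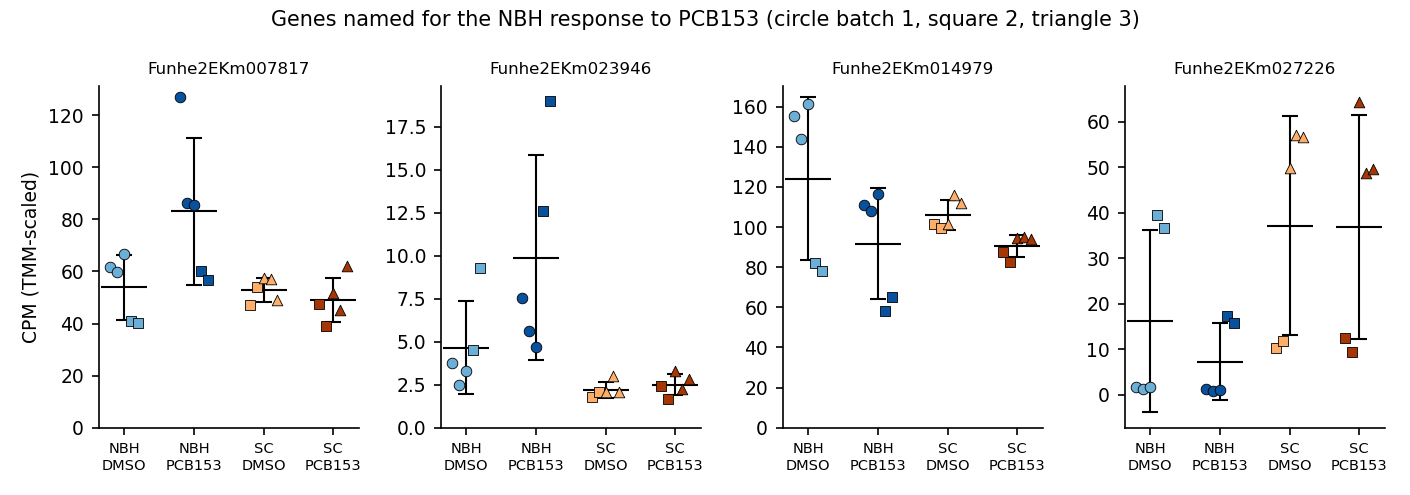
Library-size normalized counts (CPM, scaled by TMM) of Funhe2EKm007817, Funhe2EKm023946, Funhe2EKm014979 and Funhe2EKm027226 in each library of the 4 groups; symbols give the batch, horizontal lines the group mean and bars 1 SD (n = 5). Funhe2EKm014979 lies lower in PCB153 than in DMSO within each batch, and Funhe2EKm027226 spans 0.88 to 39.5 CPM among the NBH libraries.

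The number of NBH calls turned on single libraries. It was 6 genes (1 higher and 5 lower) without the PCB153 library of replicate 4. It was 10 without that of replicate 5. That fit keeps the outlying replicate 4 as the only PCB153 library of NBH in batch 2. The count was 1 without the DMSO library of replicate 4 or 5, and 0 without that of replicate 3. Without the PCB153 library of replicate 4, Funhe2EKm014979 and Funhe2EKm027226 stayed past the threshold (adjusted p = 0.0015 and 0.00182, edgeR), and Funhe2EKm023946 entered it at a log2 fold change of 1.16 (adjusted p = 0.0159, edgeR). At an unadjusted p under 0.05 there were 1321 genes in NBH, where 1144 would be reached by chance. A model with a separate mean for each group and batch called 0 genes in batch 1 of NBH and 1 in batch 2. The same model without the PCB153 library of replicate 4 called 11 in batch 1, all lower. Batch 2 then holds a single PCB153 library of NBH, so its count is not given.

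The same contrast in SC asked for the response at the reference site. No gene passed in SC (edgeR), with 609 genes at an unadjusted p under 0.05, where 1144 would be reached by chance, and 7 genes past the threshold by DESeq2. The 609 became 1310 without the PCB153 library of NBH replicate 4. The smallest adjusted p was 0.579. Among the genes at that value were Funhe2EKm012411 (Scaffold 686, 94917 to 104277), which had a log2 fold change of -1.43 (SE 0.27), and Funhe2EKm036143 (Scaffold 10061, 721855 to 757601), at -0.57 (SE 0.11). The level of Funhe2EKm012411 was 9.43 ± 3.74 CPM in DMSO and 3.34 ± 0.92 CPM in PCB153 (SD, n = 5 each), and its log2 fold change was -2.45 in batch 2 and -0.82 in batch 3. The level of Funhe2EKm036143 was 64.5 ± 10.7 CPM in DMSO and 43.9 ± 10.0 CPM in PCB153 (SD, n = 5 each). Among genes higher in PCB153, Funhe2EKm037591 (Scaffold 10098, 532347 to 549282) stood at 0.66 (SE 0.19) and Funhe2EKm007340 at 0.43 (SE 0.10), neither past the threshold. Funhe2EKm007340 is another model split over scaffolds, with 9 exons on Scaffold 287 and 1 on Scaffold 1971.

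The spread that all 4 groups share also entered the SC test, and the PCB153 library of NBH replicate 4 widened it. The common biological coefficient of variation was 0.147 with all 20 libraries and 0.086 without that library. Without it, 5 genes passed in SC and all 5 fell, among them Funhe2EKm012411 (adjusted p = 0.0102, edgeR) and Funhe2EKm036143 (adjusted p = 0.0339, edgeR). The 10 SC libraries fitted alone, also without that library, gave 0 genes (edgeR), with 1291 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0874, so the 5 calls depend on the libraries that share the spread. In the model of all 20 libraries with a separate mean for each group and batch, each batch of SC gave 1 gene past the threshold, in the downward direction. In the same model without that library, batch 2 gave 6, of which 5 were lower, and batch 3 gave 4, of which 3 were higher.

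Whether the populations responded differently was tested as the difference between the NBH and SC responses. No gene passed (edgeR), with 707 genes at an unadjusted p under 0.05, where 1144 would be reached by chance, and 0 genes by DESeq2. Funhe2EKm027226 had the smallest p among genes with the lower response in NBH. Its response was -1.02 on the log2 scale in NBH and -0.02 in SC, and the difference had an SE of 0.19 and an adjusted p of 0.755 (edgeR). Without the PCB153 library of NBH replicate 4 its difference was -1.08 (adjusted p = 0.0535, edgeR). Funhe2EKm007817 led in the other direction, with a response of 0.61 in NBH and -0.11 in SC and a difference of 0.72 (SE 0.15, adjusted p = 0.977, edgeR).

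The mean of both contrasts was tested too, which can also pass a gene that responds in 1 population alone. Funhe2EKm014979 was the 1 gene that passed, with a mean log2 fold change of -0.33 (SE 0.04, adjusted p = 0.00235, edgeR). DESeq2 called 18 genes, and with replicate number as a block there were 0. Its response in SC was -0.23 (SE 0.06), and did not pass there alone. In SC its level was 106 ± 7.53 CPM in DMSO and 90.7 ± 5.56 CPM in PCB153 (SD, n = 5 each). Without the PCB153 library of NBH replicate 4, 8 genes passed and all 8 fell, and without that of replicate 5 there were 2. Some of the 8 fell alike in both populations, such as Funhe2EKm038840 at -0.22 in NBH and -0.21 in SC. Others did not, with Funhe2EKm027226 at -1.10 and -0.02 and Funhe2EKm004070 at -0.24 and -1.03. A pass therefore does not show a response in both populations. By edgeR, the NBH and SC calls shared 0 genes, as no gene was called in SC. Fisher's exact test (two-sided, p = 1 in each direction) was therefore fixed in advance and says nothing about sharing. Without the PCB153 library of NBH replicate 4, where edgeR called 5 genes in SC, the overlap was still 0. DESeq2 called 7 genes in SC, and its overlap was 1. Of the 84 genes with an unadjusted p under 0.05 in both populations, 46 were lower with PCB153 in both, 23 were higher in both and 15 went opposite ways. There were 228 such genes without the PCB153 library of NBH replicate 4, with 141, 66 and 21. The fold changes of the responses correlated across genes at r = 0.032, and at 0.168 without the PCB153 library of NBH replicate 4. Genes are not independent replicates, so no p is given for these correlations.

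The populations themselves differed in many more genes than the treatments. In DMSO, 1162 genes passed the threshold, 584 higher and 578 lower in NBH than in SC, and 556 of them differed by at least 2-fold. These contrasts rest on batch 2, in which both populations were present. The 8 libraries of batch 2 fitted alone gave 2 genes, and the 4 genes named below fell short of the threshold there. The PCB153 library of NBH replicate 4 is among these 8 and widens the spread they share. In the model of 8 means, the log2 fold changes of the 4 genes in batch 2 were as large, at 8.88, 9.63, -7.10 and -6.77 in the order below. All 4 passed when that library was left out of the main fit. Leaving out 1 library at a time gave 678 to 2730 genes, the highest without the PCB153 library of NBH replicate 4. Funhe2EKm023904 (Scaffold 9870, 472630 to 477108) and Funhe2EKm010499 (Scaffold 490, 157966 to 160848) were the genes furthest above SC among those with an average log2 CPM of at least 1. Funhe2EKm023904 had 312 counts over the 5 NBH DMSO libraries and 0 over the 5 SC DMSO libraries, which makes it at least 120-fold higher in NBH against a floor of 3 counts over the group (adjusted p = 0.000104, edgeR). Funhe2EKm010499 had 324 counts in NBH and 0 in SC, at least 124.3-fold higher on the same floor (adjusted p = 0.000163, edgeR). Both bounds pool all batches, whereas the adjusted p rests on batch 2. In batch 2 the DMSO means of these genes were 4.29 and 7.23 CPM in NBH and 0 in SC. The furthest below SC were Funhe2EKm039700 (Scaffold 10151, 460226 to 480167) and Funhe2EKm004854 (Scaffold 172, 444004 to 445136). Funhe2EKm039700 had a log2 fold change of -6.29 (SE 0.71, adjusted p = 2.12e-05, edgeR), with 0.071 ± 0.090 CPM in NBH and 5.58 ± 4.47 CPM in SC (SD, n = 5 each). Its level in SC DMSO was 10.5 ± 0.19 CPM in batch 2 (SD, n = 2) and 2.32 ± 0.41 CPM in batch 3 (SD, n = 3). Funhe2EKm004854 had a log2 fold change of -6.13 (SE 0.64, adjusted p = 9.73e-06, edgeR), with 0.22 ± 0.19 CPM in NBH and 25.8 ± 5.07 CPM in SC (SD, n = 5 each).

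**Figure D3:**
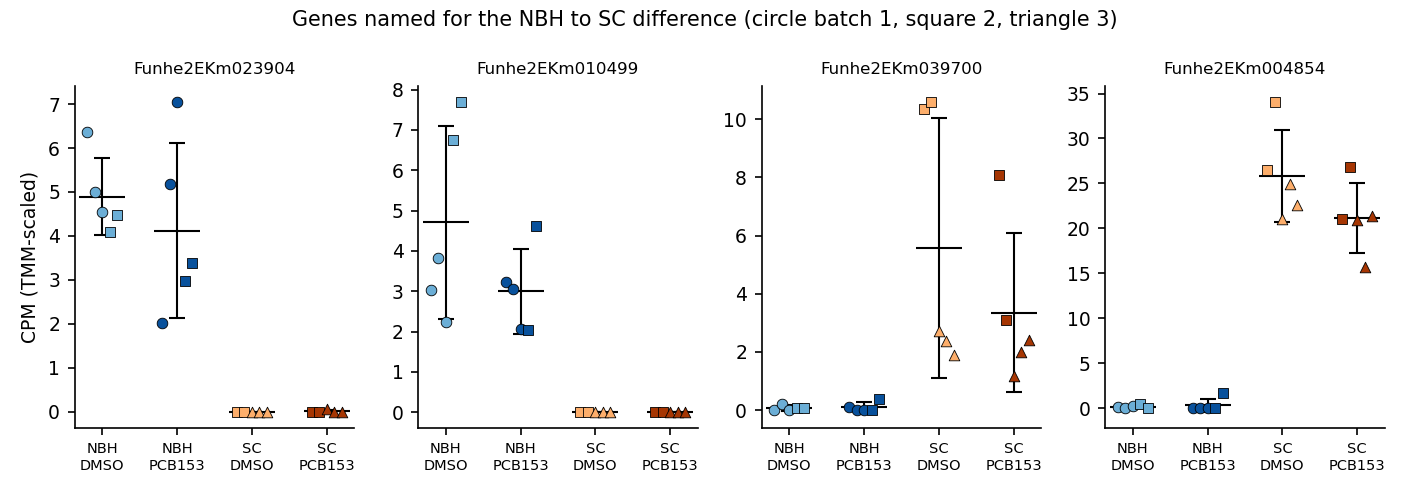
Library-size normalized counts (CPM, scaled by TMM) of Funhe2EKm023904, Funhe2EKm010499, Funhe2EKm039700 and Funhe2EKm004854 in each library; symbols give the batch, horizontal lines the group mean and bars 1 SD (n = 5). The SC libraries lie at 0 to 0.065 CPM for the first pair of genes, and the NBH libraries at 0 to 1.69 CPM for the other pair.

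Under PCB153, 1562 genes differed between the populations, 841 higher and 721 lower in NBH. Without the PCB153 library of NBH replicate 4 there were 2311, with 949 higher and 1362 lower, so the balance of directions turned on that library. The batch 2 libraries fitted alone, that library included, gave 4 genes, a count that turned on it too. The 4 genes named for DMSO also led under PCB153. Funhe2EKm010499 had 195 counts in NBH and 0 in SC with all batches pooled, at least 71.2-fold higher (adjusted p = 0.000582, edgeR). Funhe2EKm023904 had 263 counts in NBH and 1 in SC, a ratio of 288 with an exact 95% interval from 51.2 to 11414 that covers counting error only. Funhe2EKm039700 stood at -5.25 (SE 0.69) and Funhe2EKm004854 at -5.07 (SE 0.57) on the log2 scale. Of their NBH counts under PCB153, 6 of 7 and 26 of 26 came from the library of replicate 5, and the fold changes depend on it. Without it, Funhe2EKm039700 had 1 count in NBH and 224 in SC, a ratio of 155 with an exact 95% interval from 27.6 to 6166. Funhe2EKm004854 had 0 and 1473 counts, at least 341-fold lower in NBH on the floor of 3 counts. In total 828 genes passed both with and without PCB153, all of them in the same direction, while 334 passed in DMSO alone and 734 in PCB153 alone. With NBH PCB153 replicate 4 left out, these counts were 1617, again all in the same direction, 1113 and 694. The tests of the difference between the responses, with 0 genes past the threshold, give no ground to call those genes treatment-dependent. Both contrasts behind the 828 and the 1617 use the same batch estimates, so some agreement in direction is built in. In a fit with a separate mean for each group and batch, the DMSO and PCB153 contrasts of batch 2 share no library. There, 655 genes passed in DMSO and 637 of them (97.3%) had the same sign in PCB153. The counts without NBH PCB153 replicate 4 were 1797 and 1726 (96.0%).

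**Figure D4:**
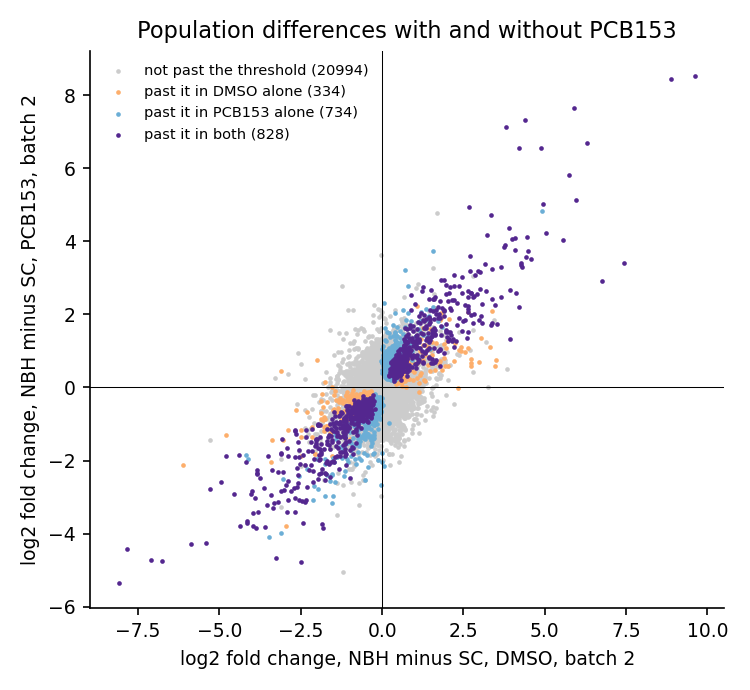
Log2 fold change of NBH minus SC in batch 2 for each of 22890 genes, in DMSO (x axis) and in PCB153 (y axis), with color showing where a gene passed an adjusted p of 0.05 in the model of all 20 libraries. The 828 genes that passed in both lie at the lower left and upper right of the plot.

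The size of the population lists also depended on single batch 2 libraries. The DMSO count was 2730 without the PCB153 library of NBH replicate 4, and 678, 761, 707 and 707 without the DMSO libraries of NBH replicates 4 and 5 and SC replicates 1 and 2. The PCB153 count was 2972 without the PCB153 library of NBH replicate 5, and 879 and 809 without those of SC replicates 1 and 2. Of the NBH PCB153 libraries of batch 2, the fit behind the 2972 holds only the outlying replicate 4.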

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

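In this part, the tests on the library of NBH PCB153 replicate 4 and the exchanges within batches of all 20 libraries were chosen after the results they bear on were seen. Of 65 groups of 5 libraries checked for a library far from the others, over 12 named genes and 5 library measures, 7 had one. Chance gives about 1 in 20 groups for independent values of a normal distribution. Each group joins libraries of different batches, and the genes were picked by their results, so that rate is no fair baseline here.

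The PCB153 library of NBH replicate 4 stood out in its distance from the NBH libraries of its own batch, with a standard deviation of 0.93 against 0.45 for the next library, PCB153 replicate 5 of NBH, whose own value includes the distance to replicate 4. On the axis from the other NBH libraries of batch 2 (position 0) to those of batch 1 (position 1), the median gene of this library lay at 0.73. The batch 1 libraries lay at 0.89 to 1.15, each left out of the axis in turn, which argues against a batch 1 library that simply carries a batch 2 label. Over 142 genes that separate the populations its median position from NBH (0) to SC (1) was 0.0016, which argues against a library of SC embryos. Removing a trend on exon length left the standard deviation at 0.92, above the 0.42 of the highest other library when replicate 4 is left out of the comparison, which argues against length bias as the whole cause. A mix of material of both batches would lie between them, yet 7.08% of 12904 genes lay beyond the range of the other NBH libraries by over 0.5 on the log2 scale, against at most 2.43% for another NBH library. That argues against such a mix as the whole cause. A pool whose embryos differed in state stays open and was not tested.

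Other libraries were far from their group in single values. SC DMSO replicate 4 had 1.66 log2 CPM of Funhe2EKm023946 where the next library had 1.16. NBH PCB153 replicate 4 had 2.56 log2 CPM of Funhe2EKm012411 where the next had 1.31. SC DMSO replicate 2 had 5.54 log2 CPM of Funhe2EKm036143 where the next had 6.03. SC PCB153 replicate 3 had -2.25 log2 CPM of Funhe2EKm023904, from 1 count, where the others had 0 counts. NBH PCB153 replicate 5 had 0.87 log2 CPM of Funhe2EKm004854, from 26 counts, where the others of its group had 0 counts. NBH PCB153 replicate 5 also had 28198 detected genes where the next library of its group had 26808, the value of replicate 4.

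Other splits of the libraries into DMSO and PCB153 were fitted in the same way. In NBH, 8 of 100 splits gave at least 2 genes, the real one included, so chance cannot be excluded for the NBH count by splits that cross batches. In all 7 others, PCB153 replicate 4 was the 1 batch 2 library in its arm, which is not so in the real design. The highest other split called 7043 genes, which points to a structure of the samples. Among the splits without that arrangement the highest count was 2, that of the real split. In SC and for the difference between responses the real count was 0, which all 100 splits reached, with at most 2 and 12 genes in another split. For the mean response, 5 of 100 splits gave at least 1 gene and the highest other gave 1018, so chance cannot be excluded there either by these splits. With labels of all 20 libraries exchanged only within batches, 1 of 60 splits, the real one, reached 2 genes in NBH (highest other 1). For the mean, 1 split, again the real one, reached 1 gene (highest other 0). These counts are of 1 or 2 genes, and the exchanges were added after the splits across batches, so chance is not excluded for either. In SC and for the difference, all 60 reached the real count of 0, with at most 1 gene in another split. For the populations, 1 of 100 splits, the real one, reached 1162 genes in DMSO and 1562 in PCB153, with at most 0 and 2 genes in another split. The other splits mix NBH and SC libraries in each arm, which widens the spread. Low counts were therefore likely there from the start, and these splits do not exclude chance. Exchanges within batch 2, where the populations meet, are too few for a share under 5%.

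With the PCB153 library of NBH replicate 4 left out and labels exchanged only within batches, there were 60 splits. The real split was the 1 that reached 6 genes in NBH (highest other 3) and the 1 that reached 5 genes in SC (highest other 2). That argues against chance for both counts, but 1 of 60 is the lowest share these splits can give, and chance is not excluded. Across all genes, the SC responses of batches 2 and 3 did not go together (r = -0.028). For the mean response, 2 splits reached 8 genes, the real one and another with 32.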

How the results depend on the processing

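Voom with library weights, the block without both NBH libraries numbered 4 and batch 2 without the PCB153 library of NBH replicate 4 were chosen after seeing the data; the cause of a change was not tested unless stated. The 2, 0, 0 and 1 calls for NBH, SC, their difference and their mean were the same with RLE and upper-quartile scaling, both filters and without robust estimation, and the population counts stayed at 1061 to 1241 in DMSO and 1462 to 1636 in PCB153. The difference between responses had 0 genes in every alternative run. DESeq2 gave 12 genes in NBH, 7 in SC, 18 for the mean and 1 in the overlap, and limma-voom 1 in NBH. DESeq2 gave no adjusted p to 18639 of the 22890 genes in NBH and to 1779 for the mean, so its counts there cover the 4251 and 21111 genes left. Without a batch term there were 0 genes in NBH and for the mean, and 6598 and 9771 between populations in DMSO (4291 higher, 2307 lower) and PCB153 (5585 and 4186), since batch 1 is NBH alone and batch 3 SC alone. At 2-fold or more the counts were 1 in NBH, 0 for the mean, 556 in DMSO and 591 in PCB153; at an adjusted p under 0.01 they were 1 in NBH, 542 and 590; at 0.10, PCB153 gave 2551.

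The NBH libraries alone gave 0 genes and the SC libraries alone 0. In the model of 8 means, which shares its spread among all 20 libraries, batches 1 and 2 gave 0 and 1 in NBH, and batches 2 and 3 gave 1 each in SC. Without NBH PCB153 replicate 4, batch 1 of NBH gave 11, and batches 2 and 3 of SC gave 6 and 4. Batch 2 of NBH then holds a single PCB153 library, so its count is not given. Batch 2 alone, with 8 libraries, gave 2 genes in DMSO and 4 in PCB153, against 3082 and 3251 with the 7 libraries left without NBH PCB153 replicate 4, where 1 NBH PCB153 library is left and is assumed to vary like the other groups. The DMSO libraries were the same in both fits, so the DMSO count moved through the spread and scaling that the groups share. Voom with library weights gave it a weight of 0.047 and called 9 genes in NBH, 17 for the mean, 2618 in DMSO and 2925 in PCB153. Leaving out each library in turn gave 0 to 10 genes in NBH, 0 to 5 in SC, 1 to 8 for the mean, 678 to 2730 in DMSO and 809 to 2972 in PCB153, with 0 for the difference and the overlap. The 10 and the 2972 came without NBH PCB153 replicate 5, where only the outlying replicate 4 is left of NBH PCB153 in batch 2. With the replicate block there were 0 genes in NBH and for the mean, and 0 still in SC; without both NBH libraries numbered 4 the block gave 1 in NBH, 1 in SC and 8 for the mean. Same-numbered libraries correlated at -0.11 to 0.17 in deviations from their batch means. In NBH batch 1 each DMSO library correlated best with its own number, though weakly (0.12, 0.17 and 0.03), and in the other batches none did. The numbers thus showed no pairing beyond the batch outside NBH batch 1, where a weak one stays open.

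No named gene reversed. Over 34 alternatives Funhe2EKm014979 in NBH ranged from -0.46 to -0.38 and passed in 28, with adjusted p up to 1, and Funhe2EKm027226 passed in 22 of 33. Of 642 gene and alternative pairs, 608 kept their side of the threshold, 25 lost it and 9 gained it. Every named population gene passed in 30 of 31 alternatives, the exception being batch 2 alone with 8 libraries. The depth limits genes of few counts, such as the near-silent population genes; the tests of the gene lists (camera, with estimated correlation or fry as alternatives, and without batch) were not run, as the identifiers have no names.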

Other observations

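The tests in this part were set before their results were seen unless stated. A few genes were read in every library of one population and close to silent in the other. With at least 1 CPM in all 10 libraries of one population and at most 3 counts in each of the 10 of the other, 3 genes were read in NBH and 1 in SC, and the split into DMSO and PCB153 libraries gave 0 such genes. Of 100 splits of the 20 libraries into 10 and 10, 1 gave as many as 4, the real one, and the highest other gave 0. Every other split puts libraries of both populations in each arm, where a gene close to silent in 1 population cannot qualify. The real count was therefore bound to stand out, and these splits do not bear on chance. Funhe2EKm010499, with 2 exons, had no count in any SC library. Whether the sequence is missing in SC, differs from the reference there or is not transcribed was not tested.

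Without the PCB153 library of NBH replicate 4, the responses of both populations leaned the same way: of 228 genes with an unadjusted p under 0.05 in both, 141 were lower with PCB153 in both, 66 higher in both and 21 opposite. The hypothesis of a small shared response was set against 2 others. An axis of quality shared with the batches may align responses. After regression on the difference between NBH batches, level and exon length the correlation across genes was 0.156, against 0.168 before. That batch difference correlated with the NBH and SC responses at only 0.098 and 0.128, so removing it could change little. Whether it reflects quality was not tested, and other axes of quality stay open. Among genes of below median level it was 0.146 and above it 0.295; an error of scaling shifts all genes alike and leaves a correlation as it is, so these values do not bear on scaling, which was not tested. Chance stays open: 3 of 60 splits within batches, the real one included, gave as large an excess of same-direction genes as the 186 observed, the highest at 230. In the model with 8 means, the correlations of NBH batch 1 with SC batches 3 and 2 were 0.118 and 0.016, and those of NBH batch 2, with 1 PCB153 library left, were 0.072 and 0.086. Of the genes with an unadjusted p under 0.05 in both, 162, 110, 115 and 112 went the same way and 31, 73, 57 and 44 opposite ways. Within NBH the batches gave 0.030, with 101 genes the same way and 26 opposite; within SC they gave -0.028, with 93 and 168. Only the pair of SC batches had more opposite than same-direction genes. Whether it differs from the other pairs was not tested, and a shared response stays open.

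Genes that differ between populations lay near one another more often than shuffled genes. In DMSO, 110 pairs of called genes 1 to 100 kb apart shared a direction, against 74.3 in 1000 shuffles (ratio 1.48), while opposite pairs numbered 65 against 74.2 (ratio 0.88). Pairs of overlapping models had a larger excess, with 23 in the same direction against 6.92 (ratio 3.32) and 6 opposite against 6.88. Scaffolds that map poorly in both populations would raise both kinds alike, and the quotient of the ratios at 1 to 100 kb was 1.69. A scaffold that maps less well in 1 population alone would raise same-direction pairs only, so the quotient does not settle mapping as a cause. Beyond 100 kb, to 500 kb, the ratio was 0.77 for same-direction pairs, but it was 0.69 for opposite pairs too. The shuffles were therefore no fair baseline at that distance, and the value does not settle whether genes split into adjacent models account for the excess. A second shuffle, added after these values were seen, kept the called genes in place and exchanged their directions. In DMSO it gave 115 same-direction pairs beyond 100 kb against a mean of 107.9 (ratio 1.07), reached by 189 of 1000 shuffles, so split models may account for the excess there and stay open. Under PCB153 it gave 262 against 228.4 (ratio 1.15), above all 1000 shuffles, which argues against split models as the whole cause there. The PCB153 calls come from the fit with NBH PCB153 replicate 4, on which the balance of their directions turned. The shuffle was not repeated without that library. Within 100 kb the same shuffle gave ratios of 1.26 in DMSO and 1.19 in PCB153. Between batches 2 and 1 of NBH DMSO, in the fit without NBH PCB153 replicate 4, there was an excess too, though a smaller one. It was 1.06 within 100 kb and 1.02 beyond, both above all 1000 shuffles. The pattern is therefore not particular to the populations. Regulation that spans adjacent genes was not tested.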
